A study of Arabidopsis thaliana with 9 samples.

How the data were processed

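Transcript levels were measured in Arabidopsis thaliana suspension culture cells of the line Alex that carried LHW and a GFP fusion of T5L1 under an estrogen-inducible system. The 9 samples formed 3 groups of 3 replicates, which were cells at 0 h, cells after 12 h with 5 µM estrogen and cells after 12 h without estrogen. Per the labels' protocols, total RNA was made into biotin-labelled sense-strand DNA, and each sample was hybridised to 1 Affymetrix array. Groups and replicate numbers came from the sample titles and treatment labels. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

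The deposited values were log2 signals per probe set, made by the authors with Affymetrix Expression Console 1.3, per the submitters' processing notes. The summarisation and the normalization between arrays were not given in the sources used here. The table held 38506 rows, of which 38310 probe sets had a value on all 9 arrays and entered the tests as deposited. The other 196 were control rows, with 98 filled only on replicates 1 and 2 and 98 others filled only on replicate 3 of every group. Equal values on 2 or 3 arrays of the same replicate number occurred for 14406 probe sets (37.6%) in replicate 3, for 406 (1.06%) in replicate 1 and for 319 (0.833%) in replicate 2. Differences of exactly 0 between replicate 3 arrays therefore occurred. Replicate 3 was treated as a processing batch of its own in added alternatives. A further 5529 probe sets repeated the values of another probe set on all arrays.

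Arrays give no read depth, so the number of arrays limits the precision. The 23 background rows, present on replicates 1 and 2, had a median log2 signal of 4.20, with single rows from 1.08 to 8.20. A level above that median is thus not shown to be clear of background. On those arrays 13187 probe sets (34.4%) had a mean below it, including 6780 of the probe sets with 1 gene (40.5%).

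The platform annotation used here named 1 gene for 16722 probe sets and several for 759, and 20829 were unnamed here. Of the probe sets with 1 gene, 16574 were found in a RefSeq gene table of the TAIR10.1 assembly, which was used only for names. No coordinates were used. For gene lists, the probe set with the highest mean over all arrays stood for a gene, which left 16411 genes.

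One linear model with a mean per group was fitted to all 9 arrays with limma 3.58.1 (lmFit and eBayes, prior degrees of freedom 3.07) in R 4.3.3. The 3 pairwise differences were tested two-sided, with Benjamini-Hochberg adjustment over 38310 probe sets and a call at an adjusted p under 0.05. Gene lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01 and with an estimated correlation. The directional and mixed tests of fry were also run. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

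The design, the rule for naming genes, 24 gene lists and a set of alternatives were fixed before the data were examined. The rule named LHW and T5L1, then the 10 largest rises and 10 largest falls among called probe sets with 1 gene and no overlap between groups (5 each for the comparison of estrogen-treated cells with 0 h), then up to 4 genes with the smallest p per list. The fixed lists held 335 entries for 329 loci. Of these, 39 loci in 18 lists had a probe set with 1 gene, and 3 lists could be tested. A further 31 lists were written after the genes with the largest changes had been seen and before the lists' own values were, and 30 of them could be tested. The result of 1 of these lists is not reported here. T5L1, LOG3, LOG4, AHP6 and SACL3 had no probe set with that gene alone and were not analysed here.

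Replicate numbers 1 to 3 recur in each group. Across probe sets, the deviations of same-numbered arrays from their group means correlated at r = 0.173 to 0.616, above 0.1 for every pair. By that rule the numbers were taken to pair the samples. Fits with the number as a block are given where they change a call. Between replicates 1 and 2, arrays of unlike number in different groups also correlated above 0.1 (r = 0.156 to 0.277). The rule therefore could not show that replicates 1 and 2 were paired. The pairing came from replicate 3, for which r was 0.445 to 0.616 between groups. Differences between replicates 1 and 2 correlated between groups at only -0.02 to 0.07, and 8 of 9 arrays matched an array of their own number best.

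Alternatives fixed before the data were examined were the replicate block, a fit of only the arrays of the 2 groups compared, quantile normalization, centring of each array on its median, removal of the dimmest 25% of probe sets, an intensity trend with a robust prior, array weights, a 2-fold minimum, an adjusted p under 0.01 and the omission of each array in turn. For lists they also held the estimated correlation and fry. Chosen after seeing the data were the processing batch block, replicates 1 and 2 only, named probe sets only, distinct profiles only, quantile normalization with the block, the scaling alternatives for lists and the added lists. The steps were tested on simulated data of 38310 probe sets with independent noise and no replicate 3 batch, tied values or correlation between genes. The simulated rates do not show how the steps behave with those features. For estrogen-treated against untreated cells at 12 h, 17 of 100 simulated log2 changes of 1 and 79 of 100 of 2 were called, with no wrong sign and 4 unchanged probe sets called. For untreated cells at 12 h against 0 h these were 21 and 81 of 100, with 7 unchanged called. The list test found a simulated shift of 0.5 in 20 genes and did not call 20 unshifted ones.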

Results

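LHW (LONESOME HIGHWAY) and T5L1 are basic helix-loop-helix transcription factors whose proteins pair and act in vascular development. The series asked which genes lie downstream of the pair, using suspension cells grown in the dark in which estrogen switches both on. Log2 signals of 38310 probe sets were compared between cells at 0 h, cells after 12 h with 5 µM estrogen and cells after 12 h without it, with 3 arrays per group. Array medians ranged from 5.28 to 6.21 over all probe sets and from 5.12 to 5.44 over probe sets with a gene name. Replicate 3 had the highest median in each group.

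**Figure D1:**
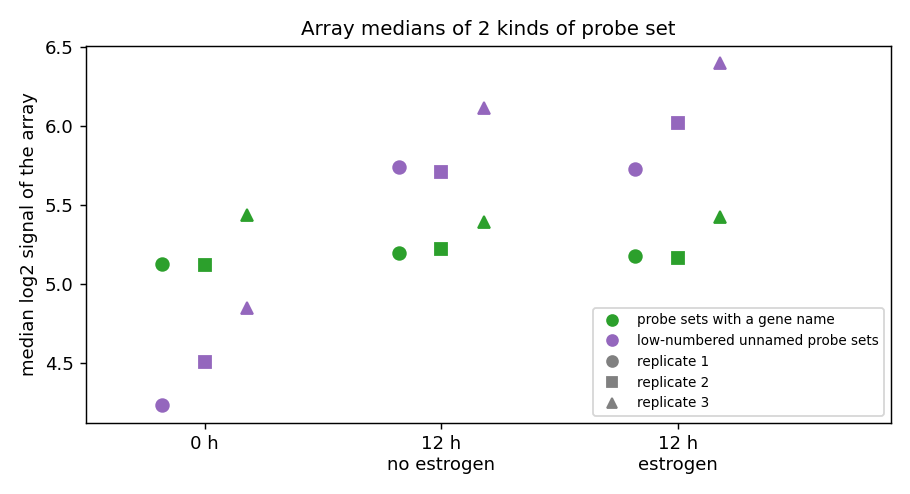
Median log2 signal of each of the 9 arrays by group, for probe sets with a gene name (green, 5.12 to 5.44) and for 7083 unnamed probe sets numbered below all named ones (purple, 4.23 to 6.40), with the marker shape giving the replicate number. The unnamed medians were 4.23 to 4.85 at 0 h and 5.71 to 6.40 on the 12 h arrays.

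The first comparison, cells with against cells without estrogen at 12 h, asked what induction did at equal time in culture. No group held estrogen-treated cells that lacked the inducible genes, or cells with only LHW or only T5L1. Effects of estrogen itself, of LHW and of T5L1 therefore cannot be told apart. LHW rose 5.73-fold with estrogen, by 2.52 (SE 0.23) from a log2 signal of 8.48 ± 0.31 (SD, n = 3 per group), with adjusted p = 0.00506. AT4G38650, a glycosyl hydrolase family 10 gene, rose 40.1-fold, from 4.34 ± 0.33 to 9.66 ± 0.13 (adjusted p = 2.5e-05), where the lower level was close to the background rows' median of 4.20. AT1G28070 rose by 1.90 (SE 0.16) and AT1G10750 by 1.71 (SE 0.19) on the log2 scale, where AT1G28070 without estrogen lay below that median (4.11), so the size of its change is uncertain. These 4 genes were the named part of 15 probe sets called higher by limma, and each was higher in 3 of 3 replicate pairs. In this fit no probe set was called lower. Some alternatives did call falls, such as 39 of 69 calls in replicates 1 and 2 and 390 of 608 with array weights. Others, such as quantile normalization, called 0. At an unadjusted p under 0.05, 403 were lower and 452 higher, together 855 of 38310. That is fewer than the share of 0.05 that tests without any effects would give. This fit had no term for replicate 3, whose arrays stood apart and widened the spread. These counts therefore cannot show whether estrogen lowered genes.

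**Figure D2:**
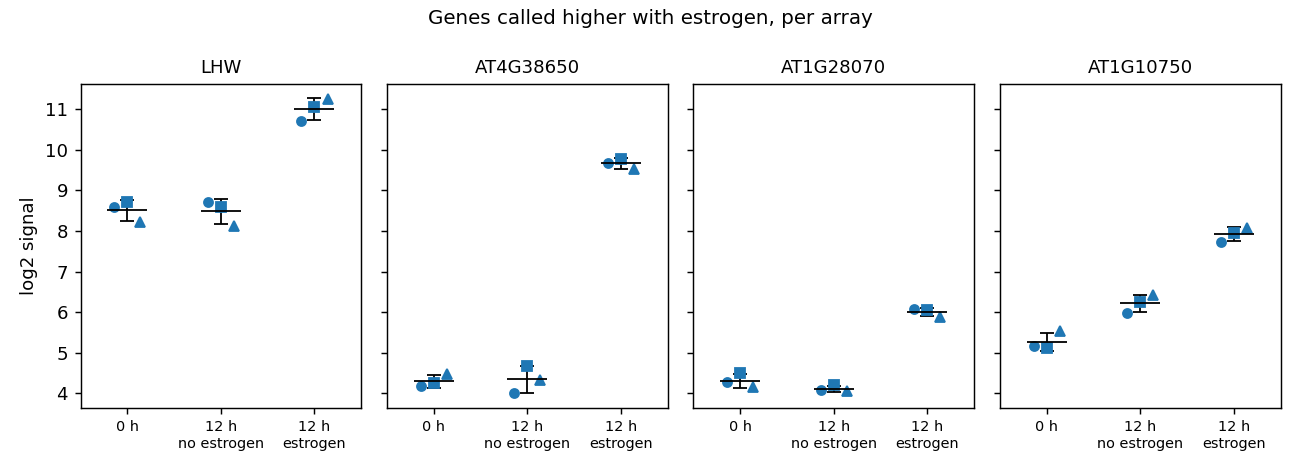
Log2 signal of the 4 named genes called higher with estrogen on each of the 9 arrays (points, shape by replicate number), with the group mean (long line) and SD (bars, n = 3). LHW averaged 8.51 at 0 h and 8.48 at 12 h without estrogen and was 5.73-fold higher with it, and AT4G38650 averaged 4.30, 4.34 and 9.66.

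The other 11 called probe sets had no gene name here. The largest rise among them was 6.35 (SE 0.49), from 7.28 to 13.63, shared by 3 probe sets with identical values, one of them 13545421. Probe set 13528308 rose by 5.70 (SE 0.45) from 2.92, below the background rows' median. The 15 probe sets held 13 distinct profiles. T5L1, the other induced gene, was not analysed here because no probe set named it alone.

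Of the 39 measured genes of the fixed lists, LHW was the 1 called with estrogen, also when adjusted over the list alone. In the list of LHW and T5L1 relatives, T5L3 (0.21, SE 0.46) and T5L2 (-0.04, SE 0.17) did not pass. That list of 3 genes passed camera (adjusted p = 0.000137, and adjusted p = 0.0224 with an estimated correlation), but its shift was carried by LHW, which the experiment induced. With the replicate block its adjusted p was 0.0135, and 0.137 with the block and an estimated correlation together. In replicates 1 and 2 alone it did not pass (adjusted p = 0.083). Its camera adjusted p ranged from 2.71e-05 to 0.083 over 16 alternatives. These left out fry and the block with an estimated correlation together. None of the 8 auxin transport and response genes was called. IAA30, an Aux/IAA gene, had the largest difference among them (1.79, SE 0.53, adjusted p = 1) and was the 1 of the 8 with an unadjusted p under 0.05, at levels of 2.35 and 4.14 that lay below the background rows' median. None of 6 procambium and cambium genes passed in limma, and 0 of them had an unadjusted p under 0.05, with CLE44 at -0.26 (SE 0.28) and PHV at -0.18 (SE 0.23). Neither list passed camera (adjusted p = 0.265 for both).

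The cytokinin response regulators ARR15 (0.14, SE 0.31) and ARR16 (0.19, SE 0.33) did not pass, with levels of 1.89 to 2.29 that lay below the background rows' median. Of genes reported downstream of LHW and its partners, DOF2.1 (-0.08, SE 0.25) and BGLU44 (-0.06, SE 0.42) were measured and did not pass. Their list also held LOG3, LOG4 and AHP6, which were probably picked from this very experiment, so the list is not independent evidence. LOG3, LOG4 and AHP6 had no probe set of their own here. The SAC51 relatives SACL1 and SACL2, the xylan synthesis gene IRX10, the phloem genes OPS and CLE45, the root hair genes EXPA7 and EXPA18, the endodermis gene SGN3 and the replication gene MCM7 differed by at most 0.27 and were not called. Neither were the aurora kinases AUR1 (0.41, SE 0.40) and AUR2, the clock gene GI, the photosynthesis gene RCA, the heat shock gene HSP22, the starvation gene MCCB and the wound response genes ZAT10 (-1.28, SE 0.83) and CML37. Over 21 alternatives ZAT10 ranged from -2.51 to -0.62, with adjusted p from 0.052 to 1. The reference genes SAND (0.04, SE 0.24) and TIP41 (0.02, SE 0.16) were not called. None of 30 added lists passed, with the lowest adjusted p at 0.0891 for the xyloglucan endotransglucosylase/hydrolases and the SWEET sugar carriers.

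With the replicate number as a block, 23 probe sets were called (20 higher, 3 lower), of which 14 were shared with the fit without the block. Added by the block were AT1G70550 (2.25, adjusted p = 0.00448), scpl16 (2.15, adjusted p = 0.0399) and AT5G02230 (1.66, adjusted p = 0.0306), named after their values were seen, along with 3 unnamed rises and 3 unnamed falls of one identical profile. LHW kept its call with the block (adjusted p = 0.042). The count was 40 (40 higher) with the processing batch as a block and 69 (30 higher, 39 lower) within replicates 1 and 2. Replicate 3 alone has 1 array per group and allows no test. Without the untreated replicate 3 array, 95 were called (22 higher, 73 lower), and with array weights, which gave replicate 3 arrays 0.244 to 0.288 against 1.16 to 2.97 for the rest, 608 (218 higher, 390 lower). The call of AT1G28070 ended after quantile normalization (adjusted p = 0.086) and median centring (0.0581), where the log2 changes were 1.78 and 1.84, within a range of 8.01e-05 to 0.086 over 21 alternatives. AT1G10750 kept its call in 13 of 21 alternatives (adjusted p 0.000602 to 0.175), while its log2 change stayed between 1.59 and 1.81 in all of them. It lost it in the fit of the 2 groups alone (0.102). It also lost it without replicate 1 or 2 at 0 h, replicate 1, 2 or 3 with estrogen or replicate 1 or 2 without estrogen (0.0637 to 0.175).

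The second comparison, cells without estrogen at 12 h against 0 h, asked what time in culture did without induction. NDB4, an external mitochondrial NAD(P)H dehydrogenase, rose 31.0-fold (4.95, SE 0.23), from 6.05 ± 0.33 (SD, n = 3 per group). EXPA15, an expansin of cell wall loosening, rose 26.7-fold (4.74, SE 0.19). Among the falls were AT5G61590, an ERF transcription factor gene, by a log2 change of -7.04 (SE 0.28) from 9.37 ± 0.45, and AT1G21400, a subunit of branched-chain keto acid dehydrogenase, at -6.92 (SE 0.28). AT1G56220, a dormancy and auxin associated gene, fell from 11.16 ± 0.45 to 4.29 ± 0.21. LHW was at -0.03 (SE 0.23) and was not called.

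The other large rises were AT4G03292 (5.99), AT1G53542 (4.93), AT1G64295 (4.78), AT5G08090 (4.77), AT4G12210 (4.70), AT1G49150 (4.65), AT4G26790 (4.49) and AT2G20835 (4.35). The other large falls were AT5G56100 (-7.01), AT5G63250 (-6.83), AT3G15450 (-6.66), AT1G19530 (-6.36), AT1G35625 (-6.36), AT4G27450 (-6.12) and AT5G24490 (-6.11). Adjusted p for these 20 named rises and falls was at most 0.000271. The 12 h levels of the 10 falls lay below the background rows' median except for AT1G56220 (4.29) and AT4G27450 (4.96), with the lowest for AT5G63250 (2.24), AT5G56100 (2.27) and AT5G61590 (2.32). The 0 h levels of EXPA15 (3.53), AT1G53542, AT5G08090, AT4G26790 and AT2G20835 also lay below it. The sizes of these changes are therefore uncertain and their order was not tested.

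In total 15063 probe sets were called, 10501 higher and 4562 lower (69.7% higher). The rises included 4029 of 7083 unnamed probe sets numbered below all named ones, of which 91.9% share a profile with another probe set. In a fit of distinct profiles only, 7356 were called higher and 4557 lower (61.7% higher). Of probe sets with 1 gene, 5000 were called, 2721 higher and 2279 lower. The split depended on the scaling, with 8966 higher and 8184 lower after quantile normalization (52.3% higher) and 7981 higher and 12637 lower after median centring (38.7% higher). The median change of all probe sets was 0.12 as deposited, -0.07 after quantile normalization and -0.35 after centring. Over probe sets with a gene name it was -0.0003, -0.18 and -0.47 in the same order. Changes below are as deposited and are to be read against these shifts.

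Of the 39 fixed-list genes, 10 were called, 5 higher and 5 lower (9 when adjusted over the list alone). T5L2 rose by 1.57 (SE 0.17) and the procambium gene DOF2.1 by 1.38 (SE 0.25), while CLE44, which encodes a peptide that restrains xylem differentiation, fell by 1.84. Of 8 auxin genes, GH3.1, an enzyme that conjugates auxin, rose by 2.73 (SE 0.36) and IAA20 by 0.68 (SE 0.23). IAA20 lay at 1.99 to 2.67, below the background rows' median, and passed in 12 of 20 alternatives (adjusted p 0.00291 to 0.598). Its call ended after quantile normalization, centring and the fit of the 2 groups alone. It also ended when 0 h replicate 2 or 3, estrogen-treated replicate 1 or untreated replicate 1 or 2 was left out (0.0657 to 0.16). IAA30 (-1.45, adjusted p = 0.0571, with the block 0.00443), LBD16 (-0.66, adjusted p = 0.0583, with the block 0.0303), GH3.3 (-1.61, adjusted p = 0.104, with the block 0.00435) and GH3.5 (-0.87, adjusted p = 0.273, with the block 0.00771) were not called, and were called with the replicate block. IAA30 and LBD16 were also called without the block in the fit of the 2 groups alone (0.0157 and 0.0494), after quantile normalization (0.0131 and 0.00173), after centring (0.00674 and 0.00113) and with array weights (0.0145 and 0.0009). Adjusted p for IAA30 ranged from 0.00125 to 0.166 over 20 alternatives, with a call without estrogen-treated replicate 2 (0.0331) or 3 (0.0125). For LBD16 it ranged from 0.0009 to 0.181 over 21, with a call without estrogen-treated replicate 3 (0.0271) or untreated replicate 3 (0.0246). SACL1 fell by 0.74, the clock gene GI by 0.91 and RCA, the Rubisco activase, by 3.20. MCCB, an enzyme of leucine breakdown raised by sugar starvation, fell by 4.0 (SE 0.24), and MCM7, a subunit of the replicative helicase, rose by 2.1 (SE 0.27). The reference genes SAND (-0.27, SE 0.24) and TIP41 (-0.08, SE 0.16) were not called as deposited, but SAND was with the block (adjusted p = 0.0436) and both were called lower after quantile normalization (0.016 and 0.034) and centring (0.00196 and 0.00442). Over 21 alternatives their adjusted p ranged from 0.00196 to 0.761 and from 0.00442 to 0.954. No fixed list passed camera (adjusted p 0.673 to 0.725).

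Of the 30 added lists, 8 passed camera at the preset correlation, 2 up and 6 down, and none passed with an estimated correlation (lowest adjusted p = 0.442). Of 106 genes of cytosolic ribosomal proteins, 102 rose, with a median of 1.60 and the largest at 4.09 (AT5G59240) and 3.02 (AT3G09680). The ribosomal list had adjusted p = 1.03e-36 and adjusted p = 0.442 with an estimated correlation. Of 17 RNA polymerase subunits, 13 rose (median 1.03), including NRPA1 (1.77) and NRPA2 (1.90) of the enzyme that makes ribosomal RNA and NRPC2 (1.85). Their adjusted p was 2.18e-06, and adjusted p = 0.442 with an estimated correlation. Both lists still passed after quantile normalization and after centring, with medians of 1.33 and 1.14 for the ribosome and 0.80 and 0.56 for the polymerases.

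Of 8 autophagy genes, 5 fell, including ATG8E (-3.26), ATG8H (-3.01) and ATG8F (-2.09), with a list adjusted p of 0.0034 and adjusted p = 0.442 with an estimated correlation. In a second list of starvation genes, which shares 2 genes with the autophagy list, 3 of 5 fell, namely ATG8E, the SnRK1 subunit AKINBETA1 (-2.40) and APG8A (-1.82), an older name of ATG8A, with adjusted p = 0.00583 and adjusted p = 0.442 with an estimated correlation. Aldehyde dehydrogenases fell in 4 of 8 cases (ALDH6B2 -2.72, ALDH7B4 -2.43), with adjusted p = 0.0447, adjusted p = 0.541 with an estimated correlation and 0.0547 with the block. Of 25 cytochromes P450, 6 fell, all of the CYP71B group (CYP71B5 -2.67), with adjusted p = 0.0431, adjusted p = 0.442 with an estimated correlation and 0.0604 with the block. Of 7 bZIP factors, 3 fell (BZIP28 -1.32, BZIP53 -1.13), with adjusted p = 0.0431 and adjusted p = 0.442 with an estimated correlation. These last 3 lists no longer passed after quantile normalization (0.0888, 0.134 and 0.105 in the order given) or centring (0.0918, 0.118 and 0.118). Their medians as deposited were -0.89, -0.15 and -0.77, and after quantile normalization they were -1.18, -0.34 and -0.98, with 5, 8 and 4 genes called lower. With the replicate block, 7 autophagy genes fell and 1 rose, 5 aldehyde dehydrogenases fell and 1 rose, and 8 cytochromes P450 fell. Of 63 plastid-encoded genes, 5 fell and 1 rose (psbT -1.15, rps16 0.59, median -0.14), with adjusted p = 0.0431 and adjusted p = 0.819 with an estimated correlation. With the block 20 of them fell and 1 rose, and after quantile normalization 43 fell and rps16 was not called higher.

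**Figure D3:**
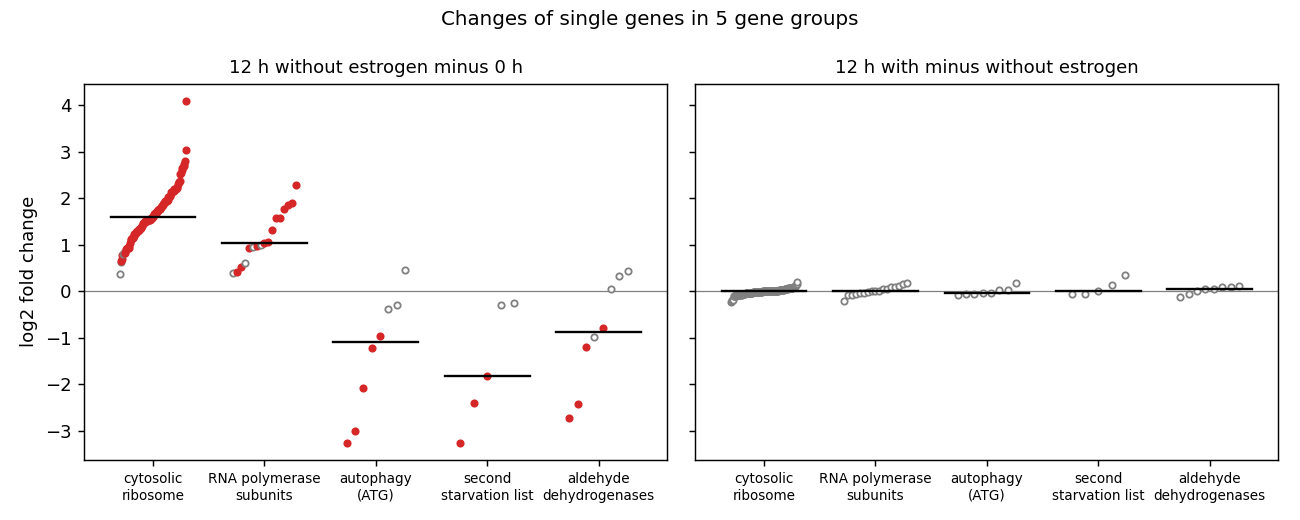
Log2 fold change of each measured gene (points, filled red where called) in 5 groups, with group medians as black lines, for 12 h without estrogen minus 0 h (left) and for 12 h with minus without estrogen (right). On the left the ribosomal median was 1.60, with 102 of 106 called, and the autophagy median was -1.09, while none of the points on the right was called.

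The third comparison, cells with estrogen at 12 h against 0 h, combined induction with time. LHW rose 5.63-fold (2.49, SE 0.23), from 8.51 ± 0.26 (SD, n = 3 per group), and AT4G38650 rose 41.2-fold (5.36, SE 0.20) from a 0 h level of 4.30, close to the background rows' median. Among probe sets with 1 gene, the largest other rises were AT4G03292 (5.97), AT1G53542 (5.33), EXPA15 (4.96) and NDB4 (4.93). Larger than some of these were unnamed rises of 5.72 (13545421, with its identical copies) and 5.58 (13528308). The largest falls among probe sets with 1 gene were AT5G56100 (-7.01), AT5G61590 (-6.93), AT3G15450 (-6.74), AT1G21400 (-6.68) and AT1G56220 (-6.64). Except for AT1G56220 (4.52), the 12 h levels of these falls lay below the background rows' median, such as 2.27 for AT5G56100 and 2.43 for AT5G61590. The 0 h levels of AT1G53542 (3.40), EXPA15 (3.53) and 13528308 (3.04) also lay below it. The sizes of these changes and of that of AT4G38650 are therefore uncertain. Limma called 15279 probe sets, 10789 higher and 4490 lower (70.6% higher). The counts were 9131 and 8412 after quantile normalization (52.0% higher) and 8050 and 14022 after centring (36.5% higher). The rises as deposited included 4291 of the unnamed probe sets numbered below all named ones. In a fit of distinct profiles only, 62.5% of calls were higher.

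Of the 39 fixed-list genes, 13 were called, 6 higher and 7 lower (11 when adjusted over the list alone). LHW, T5L2 (1.52), DOF2.1 (1.3), GH3.1 (2.76), IAA20 (0.75) and MCM7 (2.19) rose. SACL1 (-0.72), CLE44 (-2.1), RCA (-2.95), MCCB (-4.04), GI (-0.75), LBD16 (-0.72) and GH3.3 (-2.02) fell. Calls of IAA20, LBD16, GH3.3 and GI held in 14 of 20, 13 of 21, 13 of 21 and 17 of 21 alternatives. The call of IAA20 ended after quantile normalization (adjusted p = 0.0704) and centring (0.553, with a log2 change of 0.23), those of GI and LBD16 in the fit of the 2 groups alone (0.0644 and 0.0502), and that of GH3.3 among named probe sets only (0.0531). The call of IAA20 also ended without 0 h replicate 2 or 3 or estrogen-treated replicate 1 or 2 (adjusted p 0.0793 to 0.111), and that of GI without any 1 of the 3 estrogen-treated arrays (0.0688 to 0.0768). The calls of LBD16 and GH3.3 ended without any 1 of the arrays at 0 h, estrogen-treated replicate 1 or 2 or untreated replicate 1 or 2 (0.0532 to 0.149 and 0.0509 to 0.152). T5L3 (0.48, adjusted p = 0.499), AUR1 (0.76, adjusted p = 0.18) and GH3.5 (-1.09, adjusted p = 0.159) were called with the block (adjusted p = 0.0445, 0.0141 and 0.00281). AUR1 was also called without estrogen-treated replicate 3 (0.0144), as was AUR2 (0.50, adjusted p = 0.288, and 0.0365 without that array). ZAT10 (-2.23, adjusted p = 0.0614) was called in 9 of 21 alternatives (0.00129 to 0.179), including the fit of the 2 groups alone (0.00302) and the fits without untreated replicate 2 (0.0472) or 3 (0.00129). SAND (-0.23, SE 0.24) and TIP41 (-0.06, SE 0.16) were not called as deposited and were called lower after quantile normalization and centring. The list of LHW relatives passed camera (adjusted p = 0.0297, and adjusted p = 0.139 with an estimated correlation), with LHW itself among its 2 called genes. Of the added lists 5 passed at the preset correlation, 2 up and 3 down, against 9 with the block and none with an estimated correlation (lowest adjusted p = 0.405). Ribosomal proteins rose in 104 of 106 cases, with a median of 1.63.

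All 15 probe sets called higher with estrogen against untreated cells were also called higher against 0 h. Simulated groups without effects, sharing the estrogen arrays, gave a mean of 0.01 such probe sets and at most 1 in 100 simulations, and independent lists would share 4.22 higher and 0 lower. The change with estrogen against 0 h is the sum of the other 2 changes. A large rise with against without estrogen therefore tends to appear in both comparisons, and this overlap is not independent support. Of the 15, 3 were also called without estrogen against 0 h, 2 of them higher and 1 lower. AT1G10750 rose by 0.94 (SE 0.19) over 12 h without estrogen and by a further 1.71 with it, an unnamed probe set rose by 0.58 (SE 0.17) without estrogen, and another fell by 1.01 (SE 0.25). Of the probe sets called in both comparisons with 0 h, 14082 moved in the same direction (9921 higher, 4161 lower) and 1 in the opposite one. Independent lists would share 2957 higher and 535 lower. Those figures are no fair baseline, since the 2 comparisons share the 0 h arrays and differ only by the change with estrogen. Simulation without effects gave 0, but almost nothing is called in either comparison without effects, so neither simulated count measures how many real calls coincide through shared arrays. With 3 arrays at 0 h the shared arrays could not be split into parts of at least 2, so how much of the excess comes from them was not measured.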

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

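The processing batch block, replicates 1 and 2 only, named probe sets only, distinct profiles, quantile normalization with the block and the scalings of lists were chosen after seeing the data. The number of probe sets called with against without estrogen (15) was 23 with the replicate block, 608 with array weights, 40 with the processing batch block, 69 in replicates 1 and 2, 4 among named probe sets alone, where fewer were tested, and 11 to 95 when 1 array was left out. The highest came without the untreated replicate 3 array, and the other omissions gave at most 18. All 15 remained called with array weights, the batch block and replicates 1 and 2. The 15 shared with the comparison against 0 h became 342 with array weights, 32 with the batch block, 55 in replicates 1 and 2, 4 among named probe sets and 11 to 52 without 1 array. Against 0 h the counts stayed within 1.5 times of 15063 and 15279 in 22 of 23 alternatives each, and were 5145 and 5131 among named probe sets. The list of LHW relatives that passed with against without estrogen gave 0 passing lists in replicates 1 and 2 and with the mixed test of fry. Without estrogen against 0 h, 1 list passed the directional and 3 the mixed test of fry. With estrogen against 0 h, 0 passed with an estimated correlation and 3 with the mixed test. The number of ribosomal genes called higher ranged from 95 to 106 over 21 alternatives.

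No named gene that was called turned its direction. Of 743 values of named genes with against without estrogen, 732 kept their side of the threshold, 10 lost the call and 1 moved by more than 1 SD. Without estrogen against 0 h these were 1038 of 1100, with 8 lost, 42 gained and 12 moved. With estrogen against 0 h they were 817 of 891, with 26 lost, 36 gained and 12 moved. For genes of the fixed lists and genes named by the fixed rule, the replicate block changed no call beyond those given with the comparisons, while among the added lists it changed further members. Apart from the smaller set of probe sets tested, the cause was not tested. Signals near the background rows' median of 4.20 limit what the dim genes can show.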

Other observations

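The explanations that scaling accounts for the unnamed probe sets, that replicate 3 was processed apart and that relief from starvation accounts for the gene groups were tested only after the results concerned had been seen, and the added gene lists were chosen after seeing the data.

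Other gene families changed in single members between 0 h and 12 h without estrogen, although the families named here did not pass camera as lists. The directional test of fry gave adjusted p = 0.00132 for the SWEET sugar carriers, which passed, and 0.162 for the UGT glycosyltransferases, which did not. Of 14 SWEET sugar carriers, 3 fell, namely SWEET16 (-4.83, SE 0.25), SWEET2 (-4.16, SE 0.36) and SWEET17 (-1.74, SE 0.20), with a camera adjusted p of 0.242, against 6 falls after centring. Of 22 beta-glucosidases, 4 fell and 1 rose, including BGLU46 (-4.54, SE 0.47), BGLU21 (-3.99, SE 0.23) and BGLU42 (1.69, SE 0.24), with adjusted p = 0.211, against 10 falls and 1 rise after centring and 6 and 1 with the replicate block. Among 13 glutathione transferases GSTF3 (-5.25, SE 0.21) and GSTU26 (-3.29, SE 0.42) fell, while GSTU22 rose by 0.85 (adjusted p = 0.52 for the list). After centring 6 of them fell and none rose, and with the replicate block 2 fell and 3 rose. Of 51 UGT glycosyltransferases 12 fell and 4 rose, with UGT73B5 at -3.12 (adjusted p = 0.15), against 27 and 3 after centring and 14 and 8 with the replicate block. Centring moved the median change of probe sets with a gene name from -0.0003 to -0.47. Falls called only after centring, here and in the families below, are to be read against that shift.

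Among families of cell wall growth and cell division, some members rose. Of 22 expansins, EXPA9 (3.95, SE 0.32) and EXPA8 (1.93, SE 0.25) rose with EXPA15 and the dim EXPA21 fell by 0.66, for 3 rises and 1 fall as deposited against 3 and 8 after centring (list adjusted p = 0.248). With the replicate block 6 expansins rose and none fell, and EXPA21 was not called (adjusted p = 0.0629). Of 6 core histone genes, 3 rose and 1 fell, including HTB1 (1.24, SE 0.27) and AT2G28720 (-2.29, SE 0.30), with adjusted p = 0.177, and with the replicate block 4 rose and 1 fell. Of 6 tubulin genes, 3 rose, namely TUB7 (1.23), TUB1 (1.04) and TUB9 (0.76), of which 1 was still called after quantile normalization or centring (list adjusted p = 0.335). After centring 2 other tubulin genes fell, and with the replicate block 3 rose and 1 fell. In none of these families did a called member become called in the opposite direction under either scaling.

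Each comparison of 3 arrays with 3 allows 10 splits, so no share of splits can fall under 0.05. The real split alone reached its own count in each comparison (1 of 10 splits). It called 15 probe sets with against without estrogen, where the highest other split called 0, 15063 without estrogen against 0 h (highest other 0) and 15279 with estrogen against 0 h (highest other 6). Of the 4 splits that keep same-numbered arrays apart, those other than the real one called 0 in each comparison. Every other split mixes arrays of the 2 groups, so real differences widen its spread and lower its count. The splits therefore cannot tell whether the calls arose by chance.

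Unnamed probe sets numbered below all named ones (7083) rose together by a median of 1.14 from 0 h to 12 h without estrogen, with 4029 called higher and 58 lower, while the median of named probe sets was -0.00. Array scaling was argued against, since the excess over named probe sets of matched level was also 1.14 and the median stayed at 0.84 after quantile normalization. Repeated copies of one measurement were common, with 91.9% sharing a profile with another probe set, but over 1991 distinct profiles the median was still 1.05. With against without estrogen the median was 0.13. What these probe sets measure is unknown here, and no biological explanation was tested.

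Replicate 3 stood apart in all 3 groups. A difference in array scale did not account for it, since its deviations still correlated between groups at 0.43 or more after quantile normalization. Separate processing by the authors is a candidate explanation, as 37.6% of probe sets had equal values on 2 or 3 replicate 3 arrays, against 1.06% and 0.833% for the other numbers, and its control rows differed. A separate culture, day or hybridisation stays open, and the labels give none.

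Over 12 h without estrogen 102 of 106 ribosomal genes rose and 3 of 5 genes of the second starvation list fell, and neither list passed with an estimated correlation (adjusted p = 0.442 for both). Array scaling is argued against by the ribosomal median, which stayed at 1.33 after quantile normalization with a lower quartile of 0.98. In all 9 array pairs 104 of 106 genes were higher. That count alone does not argue against scaling, since a scale difference would act on every pair. A hypothesis is relief from sugar starvation, as after a transfer to fresh medium, and the second starvation list had a median of -1.82. APG8A is an older name of ATG8A, so 3 of its 5 genes (ATG8E, ATG8B and APG8A), 2 of them among its 3 falls, belong to the ATG8 autophagy family, the list is not independent of the autophagy list, and the test leaves the hypothesis open. What was done to the cells at 0 h was not given in the sources used here, so starvation relief cannot be told apart from any other effect of 12 h in culture.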
